A study of Pinus canariensis with 15 samples.

How the data were processed

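The series holds 15 one-colour Agilent microarrays of apical shoots of Canary Island pine (*Pinus canariensis*), from 5 collection dates in 1 growing season with 3 biological replicates per date, per the labels. The dates, with the group names used here, were April 15 (API1), April 30 (API2), May 22 (API3), July 3 (API4) and September 11 (API5). The trees were 5 years old (60 months) at the first date, per the labels, and had been grown outdoors after a greenhouse stage. The labels' source and tissue fields name the shoot apical meristem and an apical shoot changing from primary to secondary growth, whereas the extraction text speaks of differentiating xylem, and the difference was not resolved. Total RNA (200 ng) was amplified to cyanine 3-labelled RNA, per the labels' protocols.

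Each array carried 61339 spots, of which 59961 belonged to 19952 pine probes and 1378 were control spots. Most probes (19937) had 3 spots and 15 had 10. Only 46 probes carried a name in the gene name column (24 distinct names, some of them sequence accessions), and the description column named none. The files therefore do not pair the other probes with genes, and probe IDs stand in their place. The text patterns of the 30 gene lists written for this tissue matched 0 tested probes, under the minimum of 5, and no gene list test was run. The lists covered tubulins and actins and ribosomal proteins, among others. Tested probes with names such as Ptactin1, Ppteralfatubulin and PpterribS27 were thus missed by the patterns.

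The deposited scanner files hold linear intensity values made with Agilent Feature Extraction 10.7.3.1, per the file headers, and the processed signal in them is background-subtracted. The deposited series table holds log2 values. Its columns followed the rank order of the median spot intensity of each array (Spearman's rho across spots of 0.9998 or above), and the sorted values were alike within 2 sets, the 3 API1 arrays (column median 10.3) and the other 12 (column medians from 10.441 to 10.442). What background step and offset lay behind these values is not given in the sources used here. Per the submitters' processing notes limma was used, with no version given. Per the file headers the arrays lay on 3 slides. API1 was alone on slide 1, API2 and API3 shared slide 2, and API4 and API5 shared slide 3. Slide 1 was scanned in a later session at 5 µm per pixel, and slides 2 and 3 in an earlier session at 3 µm. Replicate numbers 1, 16 and 17, taken from the sample titles, lay in array columns 1, 2 and 3 of every slide in that order, so number and column cannot be told apart. On slides 2 and 3 the earlier date lay in array row 1 and the later date in array row 2. Within a slide, date and array row therefore cannot be told apart either.

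The values analysed were log2 of the processed signal minus each array's 75th percentile over pine spots. Spots of a probe were averaged, without spots flagged as outliers unless none was left. A probe entered the tests if it was well above background (more than 50% of its spots flagged so by the scanner software) on all 3 arrays of at least 1 date, which left 17097 probes, 14426 of them well above background on all 15 arrays. No pine spot was saturated. A linear model with date as its only factor was fitted with limma 3.58.1 (R 4.3.3) to all 15 arrays, with empirical Bayes moderation, a moderated F test over the dates and a moderated test for each of 5 comparisons. p-values were adjusted by Benjamini-Hochberg within each test, with a threshold of 0.05. All tests were two-sided. These choices, the alternatives and the naming rule were fixed before the data were examined. Reading the flag by the majority of a probe's spots and not counting accessions as gene names were settled once the files had been seen. API5 minus API2, the F test over the 4 dates of the earlier scan session, the GC correction, array weights and the fits without particular doubted arrays were added after the data had been seen.

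Probes were named by rule. For each comparison the rule took probes with an adjusted p under 0.05, an absolute log2 difference of at least 1 and the same sign in all 3 replicate numbers, then up to 10 gene names per direction (the probe with the smallest F test p-value standing for a name) and, among probes without a gene name, the 2 IDs with the largest rise and the 2 with the largest fall. Where a probe was not well above background on any array of a date, the fold is a lower bound. It is the mean of the brighter date against the dim date's mean of, per array, the higher of the probe's own value and the lowest value among probes well above background.

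Whether the replicate numbers pair the samples across dates was checked on deviations from the date means. All 30 pairs of arrays with the same number correlated across probes, with r from 0.17 to 0.54, while the 60 pairs with different numbers lay between -0.39 and 0.09. Since the deviations of a date cancel out by construction, the lower values for different numbers follow from those for the same number and add no support. On the same-number correlations the numbers were taken to pair the samples. The fit with the number as a block is given where it moves a count by more than 1.5 times. Differences, SEs and adjusted p-values of single probes are from fits without the block. Probes just short of the threshold were thus judged without the pairing. The labels do not say what a number stands for.

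The procedure was tested on simulated data with the spread of the real probes, 17097 probes and 200 changed ones per comparison. For API2 minus API1, 79% of probes changed by 2 on the log2 scale and 13% of those changed by 1 were recovered, with 4 false calls. For API3 minus API2 the shares were 76% and 13%, with 2 false calls, and for API4 minus API3 85% and 12%, with 6. The simulated noise was independent between arrays, and few probes changed. The shares therefore do not give the recovery for comparisons in which many probes differ, such as API2 minus API1. The number of arrays limits the precision. The alternatives were normexp background correction with an offset of 50, quantile normalization, scaling to the median, the deposited table, no filter or a filter on all 15 arrays, a variance trend with robust moderation, the replicate block, stricter thresholds, fits on the 6 arrays compared, slide as a block, and leaving out each array in turn.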

Results

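Gene expression was measured in apical shoots of Canary Island pine, a conifer of the Canary Islands, at 5 dates between mid April and mid September. Each date had 3 arrays, with replicate numbers 1, 16 and 17, and 17097 probes were bright enough to be tested. The share of pine spots well above background was 75.2% to 78.9% on the 3 arrays of April 15 and 82.9% to 87.7% on the other 12. Arrays of the same date correlated across probes with r from 0.88 to 0.96, and no pair held identical values. The labels call the replicates biological, without saying whether each was a separate tree. Where no block is named, p-values measure the spread between these samples within dates and ignore the pairing. The same 3 numbers recur at every date, so the 15 arrays may not be independent. On April 30 replicate 1 (API2 replicate 1) the E1A control spots, which no pine RNA was meant to bind, lay 2.46 above the negative control spots on the log2 scale, against at most 0.24 on the other 14 arrays.

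**Figure D1:**
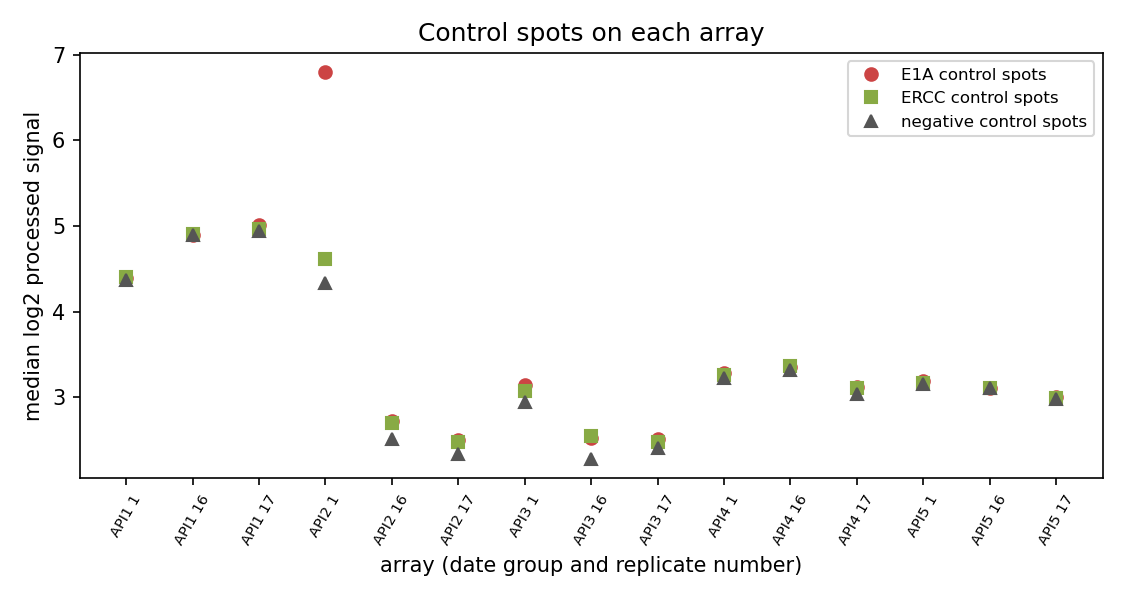
Median log2 processed signal (vertical axis) of E1A, ERCC and negative control spots on each of the 15 arrays (horizontal axis, date group and replicate number). The E1A spots lie 2.46 above the negative control spots on API2 replicate 1 and at most 0.24 above them on the other 14 arrays.

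Probe signals in the shoot differed widely among the dates. Of the 17097 probes, 6729 (39.4%) differed among the 5 dates in limma's moderated F test. The first principal component held 37.3% of the variance and placed the April 15 arrays at -106 to -98.0, the April 30 arrays at -25.6 to -7.37 and the September arrays at 46.6 to 63.2. On the second (19.7%) the April 15 arrays, at 35.9 to 42.4, lay on the side of September, at 10.3 to 99.6, and away from April 30, at -51.4 to -41.6. September replicate 16, at 99.6, lay apart from the others of its date. July 3 replicate 1, at 30.0 and -29.4, lay beside May 22 replicate 17, at 30.8 and -33.1, and away from the other July arrays, at 68.2 and 28 and at 68.7 and 17.8. Among the 4 later dates, scanned in 1 session, 1298 probes differed, and 2740 with the replicate number as a block; leaving out 1 array gave 192 (without API2 replicate 16) to 1782. April 15 alone lay on its own slide and in its own scan session, so for that date season and batch cannot be told apart. Of the later dates, April 30 and May 22 lay on slide 2 and July 3 and September 11 on slide 3. Differences between these slides cannot be told apart from the season either. The 2 differences within slides gave 27 probes in a joint F test, where date cannot be told apart from array row.

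**Figure D2:**
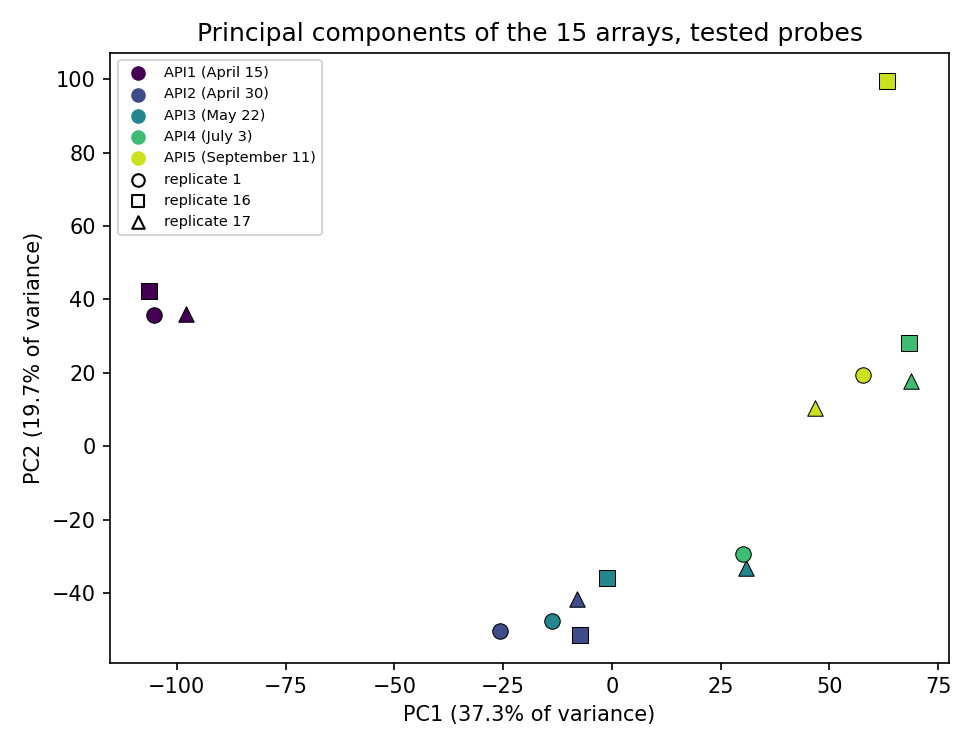
Scores of the 15 arrays on the first and second principal components (percent of variance on each axis) over 17097 tested probes, coloured by date, with the marker giving the replicate number. The April 15 arrays lie between -106 and -98.0 on PC1, and September replicate 16 lies at 99.6 on PC2.

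The first comparison, April 30 minus April 15 (API2 minus API1, 15 days), asks what changed in the shoot early in the season. Some probes named for glyceraldehyde-3-phosphate dehydrogenase and 1 of the 3 tested probes for actin, a protein of the cytoskeleton, were higher on April 30. PsGA3PDH (probe CUST_18_PI416083892) rose by 1.81 ± 0.27 on the log2 scale (SE, n = 3 per date; limma adjusted p = 0.000694), from 0.72 ± 0.29 to 2.53 ± 0.32 (SD). PthGA3PDH (CUST_7_PI416083892) rose by 1.65 ± 0.26 (adjusted p = 0.000998) and Ptactin1 (CUST_1_PI416083914) by 1.56 ± 0.23 (adjusted p = 0.00063). The other 2 actin probes did not pass. PcontortaActin CUST_30_PI416083892 had a difference of 1.67 (adjusted p = 0.053), and CUST_28_PI416083892 (adjusted p = 0.0659) was not well above background on April 15. PpterGs1b (CUST_12_PI416083914), a name used for cytosolic glutamine synthetase in pines, rose by 1.36 ± 0.21 (adjusted p = 0.000866). Ppterrd21 (CUST_13_PI416083914), a name used for a dehydration-responsive cysteine protease, rose by 1.60 ± 0.27 (adjusted p = 0.00132).

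Not all probes of these names passed. The 3 PthGA3PDH probes rose, by 1.65, 2.10 and 2.08. Of the 3 PsGA3PDH probes 2 rose, by 1.81 each, and CUST_16_PI416083892, well above background on 0 of the 3 April 15 arrays and 1 of the 3 April 30 arrays, was too dim to compare with them. The PsGA3PDH probe CUST_18_PI416083892 and the PthGA3PDH probe CUST_7_PI416083892 share a run of 40 bases, and the PthGA3PDH probe CUST_8_PI416083892 shares 20 bases with each of the other 2 of its name, so these are not independent measurements. The 8 tested probes named PscpGA3PDH1 and PscpGA3PDH2 and the 3 named PsGapC1 did not pass in this comparison, with differences from -0.79 to 0.60. Of the 38 tested probes with an entry in the gene name column, 8 rose, 2 fell and 28 did not pass. The 2 that fell include CUST_1_PI428261289, described below, whose entry is only a sequence accession, so its target is not known here. The PsitcheIF4B2 probe CUST_25_PI416083892, named for a translation initiation factor, fell by 0.77 ± 0.25 (adjusted p = 0.0383), while the other 2 probes of that name had differences of 0.17 and -0.15.

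Over all probes 3945 differed, 2571 higher and 1374 lower on April 30. The probes named by the rule include CUST_7638_PI427606166 (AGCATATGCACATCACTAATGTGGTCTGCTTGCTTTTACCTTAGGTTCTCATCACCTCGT), not well above background on April 15 and at least 30.0-fold higher on April 30 (adjusted p = 3.83e-06). CUST_3579_PI427606162 rose by 6.17 ± 0.77 (adjusted p = 0.000195) and was well above background on 1 of the 3 April 15 arrays. CUST_1_PI428261289 (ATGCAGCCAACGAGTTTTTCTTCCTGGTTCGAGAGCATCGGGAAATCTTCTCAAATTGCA) fell from 6.0 ± 0.24 to -1.57 ± 0.92, a difference of -7.58 ± 0.51 (adjusted p = 3.83e-06). Its mean stayed between -1.57 and -0.97 at the 4 later dates. CUST_1678_PI427606222 was at least 46.6-fold lower on April 30, where it was not well above background (adjusted p = 0.0083). Its April 15 arrays lay far apart, at 0.52, -1.94 and -4.28, so the size of this fall is imprecise. The balance of directions depended on the processing. The share of calls that were higher was 65.2%, against 50.9% with median scaling (1988 higher, 1916 lower), 54.6% with quantile normalization (2054 and 1709) and 50.6% with normexp correction (1704 and 1662), 49.9% without the filter (2571 and 2582) and 58.8% for probes bright on all 15 arrays (1807 and 1268), and the median difference of all probes moved from 0.08 to -0.06 with median scaling. Without API2 replicate 16 the count fell to 2324.

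**Figure D3:**
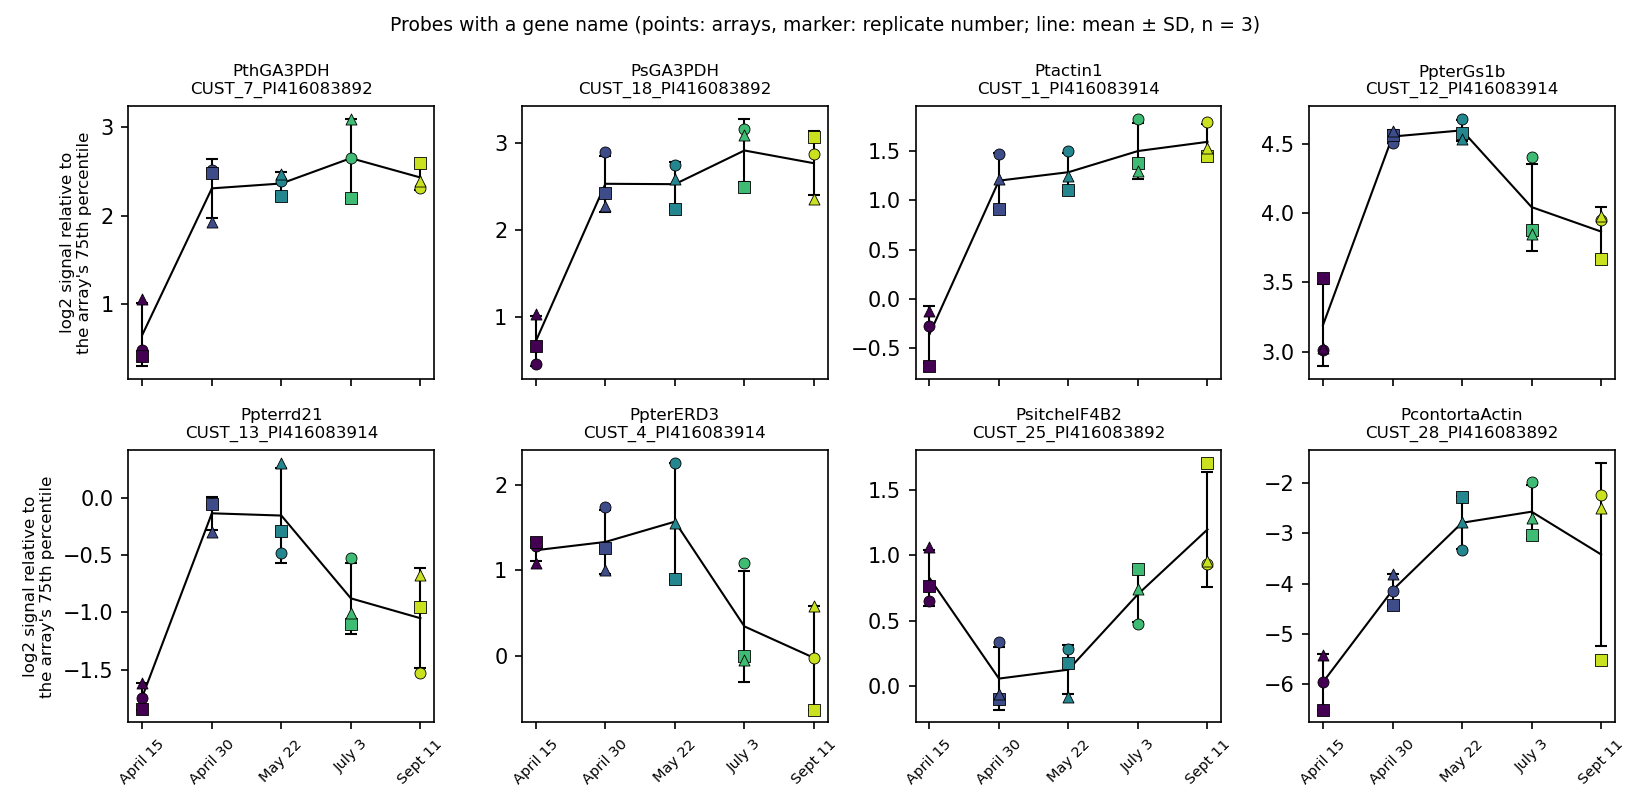
Log2 signal relative to each array's 75th percentile (vertical axis) by date for 8 probes with a gene name; points are arrays and lines join date means ± SD (n = 3). PsGA3PDH was 0.72 ± 0.29 on April 15 and 2.53 ± 0.32 on April 30, and PpterERD3 was 1.57 ± 0.68 on May 22 and -0.02 ± 0.61 on September 11.

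From April 30 to May 22 (API3 minus API2, 22 days, both dates on 1 slide) 1 probe passed, CUST_2091_PI427606222 (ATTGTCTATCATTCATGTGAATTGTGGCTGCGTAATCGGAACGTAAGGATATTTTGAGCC). It fell from -4.47 ± 0.52 to -8.04 ± 0.62, a difference of -3.57 ± 0.34 (limma adjusted p = 0.00126), and was well above background on all 3 April 30 arrays and on 1 of the 3 May arrays. It was not well above background on any array of April 15, July 3 or September 11. PsGA3PDH (CUST_18_PI416083892) differed by -0.0044 ± 0.27 and Ptactin1 by 0.09 ± 0.23, with none of the 38 probes with an entry in the gene name column called in limma's test. At an unadjusted limma p under 0.05 there were 887 probes, and 1288 with the replicate number as a block, where 855 would be expected if none changed. On simulated data this comparison recovered 13% of probes changed by 1 on the log2 scale and 76% of those changed by 2, so the single call does not show that the dates were alike. The deposited table and the fit on the 6 arrays alone ended the call of CUST_2091_PI427606222, with differences of -1.54 (adjusted p = 0.0997) and -3.57 (adjusted p = 0.506). On the 6 arrays the size of the fall is the same by construction. The dates lay in different array rows of the slide, so row and date cannot be told apart.

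From May 22 to July 3 (API4 minus API3, 42 days) 56 probes rose and 69 fell. CUST_6658_PI427606162 (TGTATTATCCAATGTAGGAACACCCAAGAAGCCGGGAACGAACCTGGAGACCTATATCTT) rose by 4.75 ± 0.99 (limma adjusted p = 0.0474), from -2.38 ± 1.26 to 2.37 ± 1.41. CUST_11952_PI427606166 rose by 4.34 ± 0.70 (adjusted p = 0.0285), having been well above background on 2 of the 3 May arrays. CUST_15039_PI427606162 fell by 5.25 ± 1.08 (adjusted p = 0.0474), to well above background on 1 of the 3 July arrays. CUST_283_PI427606166 (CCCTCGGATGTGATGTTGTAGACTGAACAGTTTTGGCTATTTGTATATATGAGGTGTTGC) fell by 3.72 ± 0.77 (adjusted p = 0.0474), from -1.45 ± 1.45 to -5.17 ± 1.5. Of the probes with gene names, PpterERD3 had a difference of -1.22 ± 0.40 (adjusted p = 0.139), short of the threshold. The 125 calls were not firm, and the 4 probes named here lost theirs in 6 to 11 settings each. Their direction did not change, as is likely for probes chosen by large differences in these arrays. The count was 372 with the replicate number as a block, 0 with the 6 arrays alone, 0 without API3 replicate 16 or without API4 replicate 16, and 790 without API4 replicate 1. The balance was not firm either, with 96 higher and 91 lower without API3 replicate 17. Where limma called 0 probes, 2811 (6 arrays), 2589 (without API3 replicate 16) and 2084 (without API4 replicate 16) had an unadjusted p under 0.05. The dates lay on different slides of 1 scan session, so slide and date cannot be told apart.

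From July 3 to September 11 (API5 minus API4, 70 days, both dates on 1 slide) 23 probes rose and 39 fell. These dates lay in different array rows of that slide, so row and date cannot be told apart. CUST_283_PI427606166, which had fallen by July, rose by 6.10 ± 0.77 (limma adjusted p = 0.0042) to 0.93 ± 1.12. This rise and the less firm fall before it share the July arrays and are not independent observations. CUST_16258_PI427606162 (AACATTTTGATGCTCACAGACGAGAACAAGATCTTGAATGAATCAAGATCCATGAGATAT), not well above background at any earlier date, was at least 13.2-fold higher in September (adjusted p = 0.000959). CUST_7638_PI427606166, which had risen between the April dates, was at least 17.2-fold lower in September than in July (adjusted p = 4.19e-05), and again not well above background. CUST_948_PI427606222 fell by 5.48 ± 0.96 (adjusted p = 0.0321) and was well above background on 1 of the 3 September arrays. Its call was lost in 7 settings, among them the 6 arrays alone (-5.48, adjusted p = 0.365) and the fit without API4 replicate 17 (-4.54, adjusted p = 0.145). No probe with an entry in the gene name column passed in limma's test. PsGA3PDH (CUST_18_PI416083892) differed by -0.15 ± 0.27 and PpterERD3 by -0.37 ± 0.40. The 62 calls were 126 with the replicate block, 3 with the 6 arrays alone, 20 without API2 replicate 1 and API5 replicate 16, where the balance turned to 11 higher and 9 lower, 19 without API5 replicate 16, and 14 to 139 over all arrays left out in turn (without API4 replicate 17 and without API5 replicate 17).

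**Figure D4:**
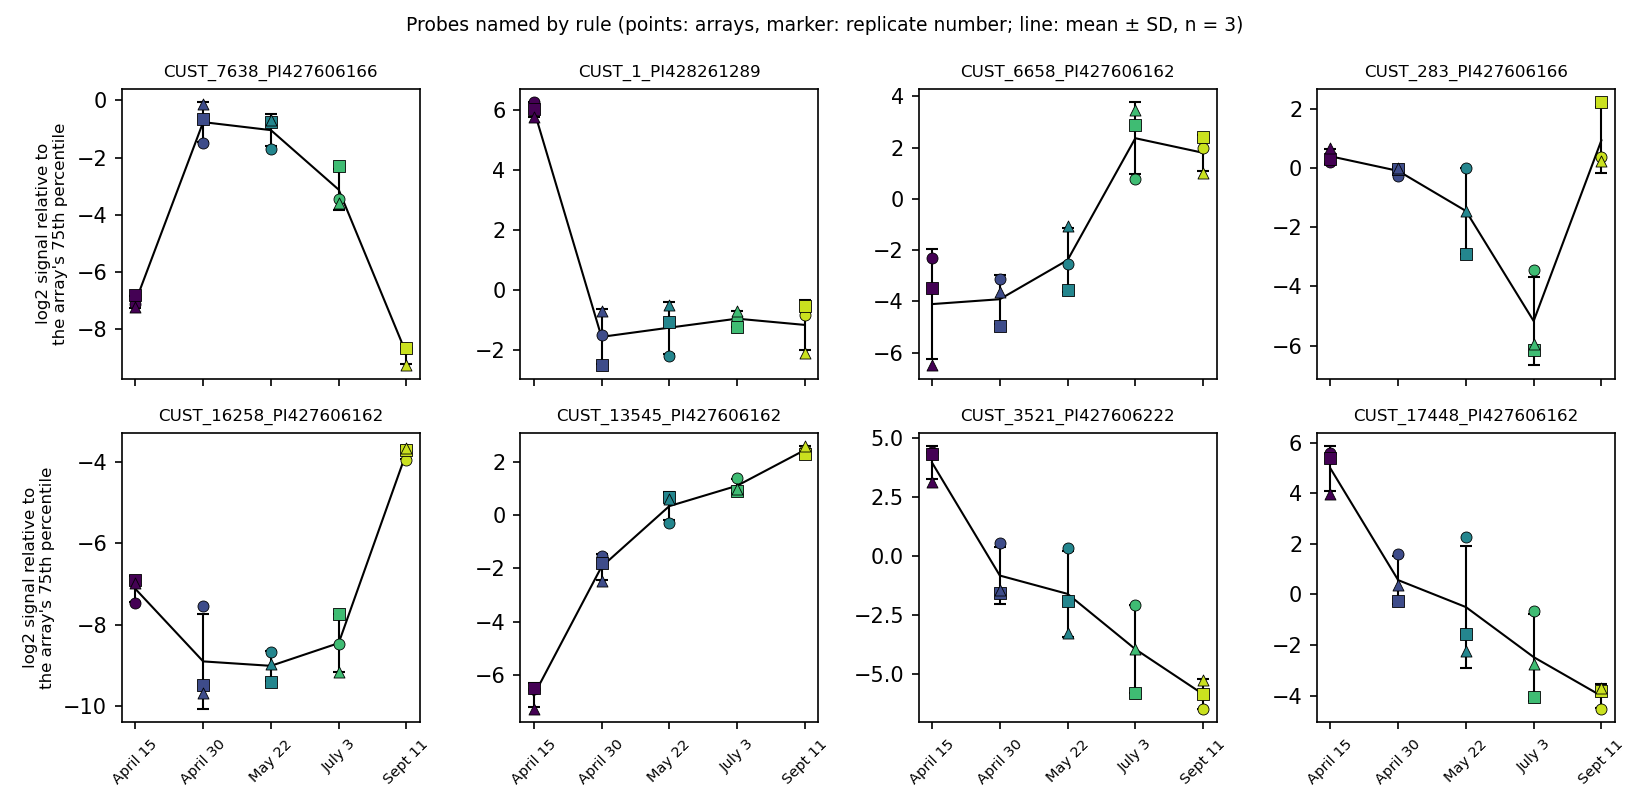
Log2 signal relative to each array's 75th percentile (vertical axis) by date for 8 probes named by rule; points are arrays and lines join date means ± SD (n = 3). CUST_13545_PI427606162 went from -6.77 ± 0.45 on April 15 to 2.43 ± 0.15 on September 11, and CUST_283_PI427606166 was lowest on July 3, at -5.17 ± 1.5.

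Across the whole season, September 11 minus April 15 (API5 minus API1, 149 days), 3163 probes were higher and 2695 lower. This balance turned with the processing, to 2702 higher and 3210 lower with median scaling, 2444 and 2681 with normexp correction, 2780 and 2908 with quantile normalization, 3159 and 4320 without the filter and 2321 and 2525 for probes bright on all 15 arrays. CUST_13545_PI427606162 (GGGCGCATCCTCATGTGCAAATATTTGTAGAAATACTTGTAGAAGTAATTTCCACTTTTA) had a higher mean at each date than at the one before, from -6.77 ± 0.45 to 2.43 ± 0.15. It was not well above background on April 15 and at least 274-fold higher in September (limma adjusted p = 3.7e-09). CUST_11414_PI427606166 was at least 279-fold higher (adjusted p = 0.000574). CUST_3521_PI427606222 fell by 9.79 ± 0.96 (adjusted p = 1.82e-05), from 3.95 ± 0.71 to -5.85 ± 0.62, and was well above background on 2 of the 3 September arrays. CUST_17448_PI427606162, which shares a run of 18 bases with it, fell by 8.99 ± 1.04 (adjusted p = 6.24e-05). The bases just before that run are largely alike as well, so the falls of these probes are not independent measurements. Both had a lower mean at each date than at the one before.

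Some GA3PDH probes and the Ptactin1 probe that were higher on April 30 than on April 15 were higher in September too, and the PscpGA3PDH1 probe CUST_6_PI416083914 was lower, by 0.87 ± 0.265 (limma adjusted p = 0.0225). The other PscpGA3PDH1 probes, with differences of -0.32, 0.33 and -0.36, did not pass. PsGA3PDH (CUST_18_PI416083892) rose by 2.05 ± 0.27 (limma adjusted p = 0.000161), Ptactin1 by 1.95 ± 0.23 (adjusted p = 7.55e-05) and PthGA3PDH (CUST_7_PI416083892) by 1.77 ± 0.26 (adjusted p = 0.000332). PcontortaActin (CUST_28_PI416083892), not well above background on April 15, was at least 4.55-fold higher (adjusted p = 0.0112), although its September SD was 1.83. The PcontortaActin probe CUST_30_PI416083892 rose by 1.95 ± 0.58 (adjusted p = 0.0203). PpterERD3, named for an early response to dehydration, fell by 1.26 ± 0.40 (adjusted p = 0.0285). Its call was lost in 6 settings, among them the fit without API2 replicate 1 and API5 replicate 16 (-0.95, adjusted p = 0.117). Of the 38 tested probes with an entry in the gene name column 11 rose, 3 fell and 24 did not pass. This comparison crosses slide and scan session.

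September 11 minus April 30 (API5 minus API2, 134 days), added after the data had been seen, stays within 1 scan session but crosses slides. Here 1252 probes were higher and 1575 lower. CUST_11636_PI427606166 rose by 7.68 ± 1.37 (limma adjusted p = 0.00521), having been well above background on 1 of the 3 April 30 arrays, and CUST_13238_PI427606162 rose by 5.92 ± 0.76 (adjusted p = 0.00107). CUST_7638_PI427606166 was at least 88.5-fold lower (adjusted p = 5.1e-07) and CUST_15608_PI427606162 fell by 6.63 ± 1.12 (adjusted p = 0.00421). Of the 38 tested probes with an entry in the gene name column 2 rose, 3 fell and 33 did not pass. The PsitcheIF4B2 probe CUST_25_PI416083892 rose by 1.14 ± 0.25 (adjusted p = 0.0105) and PpterERD3 fell by 1.35 ± 0.40 (adjusted p = 0.0369). The other PsitcheIF4B2 probes, with differences of -0.10 and 0.64, did not pass. PpterGs1b and Ppterrd21, which had risen between the April dates, fell by 0.69 (adjusted p = 0.0429) and 0.92 (adjusted p = 0.0342), while PsGA3PDH differed by 0.24 ± 0.27 (adjusted p = 0.577) and Ptactin1 by 0.39 ± 0.23 (adjusted p = 0.257). The falls of PpterGs1b and Ppterrd21, smaller than 1 on the log2 scale, were not followed through the other settings. Their rise between the April dates crosses slide and scan session. Without API2 replicate 1 and API5 replicate 16 the count fell from 2827 to 467 and the balance turned, to 252 higher and 215 lower. Neither the PsitcheIF4B2 probe CUST_25_PI416083892, with a difference of 1.02 (adjusted p = 0.0505), nor PpterERD3, with -0.85 (adjusted p = 0.308), passed. Over all settings PpterERD3 lost its call in 8 and CUST_25_PI416083892 in 2.

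**Figure D5:**
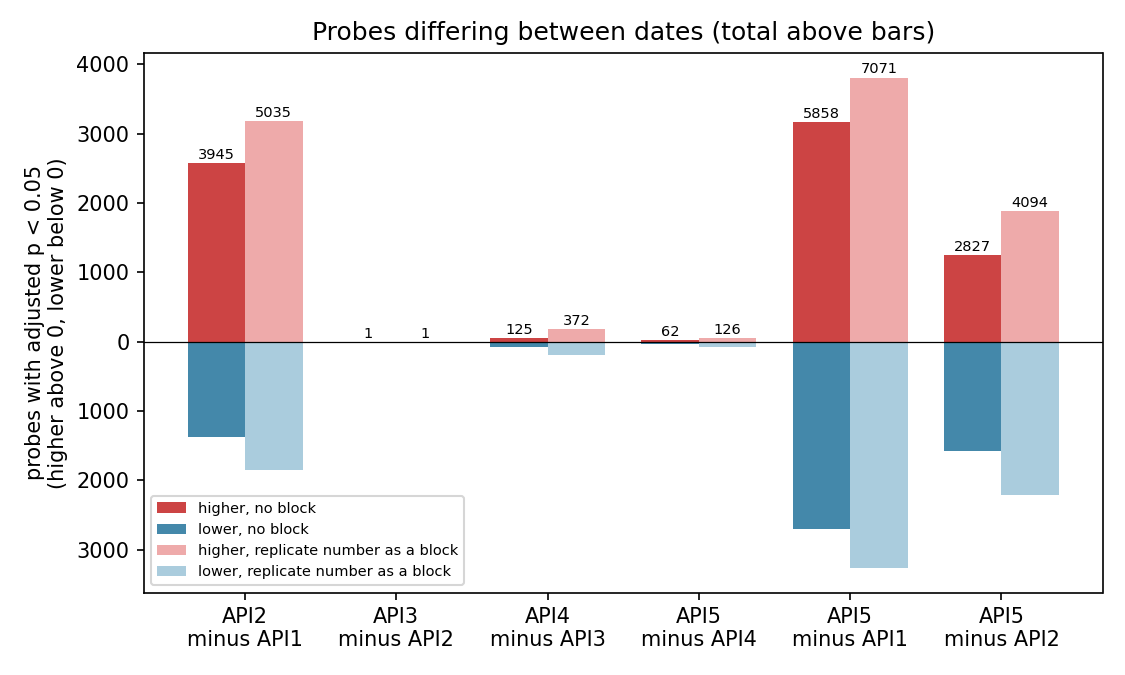
Number of probes with a limma adjusted p under 0.05 (vertical axis, higher probes above 0 and lower probes below) for 6 comparisons between dates, without a block (dark bars) and with the replicate number as a block (light bars). The totals were 3945 and 5035 for API2 minus API1, and 1 and 1 for API3 minus API2.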

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

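The tests of the control spots, of brightness, of how the calls of API2 minus API1 arose in part, and of other splits were chosen after the results were seen. The tests on GC content and relation to later dates were chosen before their results were seen. Groups of 3 arrays were not screened for single outlying samples.

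On API2 replicate 1 the E1A control spots, which carry an adenovirus sequence used for spike-in controls, gave a signal outside the pine measurements. Their median lay 2.46 above that of the negative control spots of the same array on the log2 scale, against at most 0.24 on the other 14 arrays, and 8 of the 10 E1A probes lay more than 1 above it. On this array alone 124 pine probes were well above background, against at most 39 for any other array, as extra labelled material on it would give. The background of this array was raised as well. Its negative control net signal was 103, against 49.0 to 59.4 on the other arrays of its session, the median log2 signal of its negative control spots 4.33 against 2.28 to 3.32, and its local background 43 against 35 to 39. What part a raised background had, and what any extra material was, stays open, and no biological explanation was tested.

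The 3945 probes that differed between April 15 and April 30 may reflect the season, the slide and scan session, or both. The April 15 arrays had a local background of 83 to 85 units against 35 to 43 on the others, and the dimmest 4275 tested probes had a median difference of 0.26 against 0.0029 in the brightest 4274. A background effect on dim probes as the whole cause is argued against by the brightest 4274, of which 11.5% passed with an absolute log2 difference of at least 1. GC content as the whole cause is argued against by the 4944 calls left after a GC correction with the replicate block (5035 without the correction). If slide and session were the only cause, no relation to API5 minus API3, dates of the other session, would be seen, whereas r above 0.1 had been set down as the sign of a shared season. Across probes r was -0.11 (-0.16 to -0.07 with each array left out), of the opposite sign and on both sides of the bound of -0.1, so neither was met. API5 minus API3 crosses slides as well, and the value decides nothing. The slide and session as a part of the cause cannot be told apart from the date, since no slide holds both dates.

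Other splits of the arrays tested whether grouping by date could be chance. For the 5 dates, 1 of 100 splits, the real one, gave 6729 probes, and the highest of the others gave 5. For the 4 dates of the earlier session 1 of 100 gave 1298, with 223 as the highest other. An arbitrary grouping of the arrays thus did not give such counts. The splits ignored slides and replicate numbers. Since each date lay on 1 slide, a slide difference would set the real split apart as well, and the splits cannot part date from slide. With 3 arrays against 3 the 10 splits are too few for a statement on chance. The real split and the highest other gave 3945 and 0 probes for API2 minus API1, 1 and 1 for API3 minus API2 (2 splits with 1 call), 125 and 0 for API4 minus API3, 62 and 8 for API5 minus API4, 5858 and 1 for API5 minus API1, and 2827 and 0 for API5 minus API2. The splits that, like the real one, part all 3 pairs of equal numbers gave at most 0 apart from the real one.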

How the results depend on the processing

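The settings with GC correction, array weights, the 12 arrays of 1 session or both doubted arrays left out (API2 replicate 1 and API5 replicate 16) were chosen after seeing the data, as were all those of the F test over 4 dates and of API5 minus API2. Where no construction is named, the cause was not tested. Slide as a block tested nothing. Each date lies on 1 slide, so for API3 minus API2 and API5 minus API4 the block gives the same fit by construction, and for no other comparison can it be fitted. The gene list alternatives were not run, since the text pattern of no list matched the name of a tested probe.

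At an adjusted p under 0.01, a stricter threshold, the counts were 3164 (F, 5 dates), 90 (F, 4 dates), 1801 (API2 minus API1), 0 (API4 minus API3; 3138 at an unadjusted limma p under 0.05), 3206 (API5 minus API1), 657 (API5 minus API2) and 13 (API5 minus API4). The replicate block, which uses the pairing, gave 8632 (F, 5 dates), 2740 (F, 4 dates), 372 (API4 minus API3) and 126 (API5 minus API4). With GC correction added these were 8496, 2571, 335 and 129. The block alone also gave 2364 for API4 minus API2 (1380 without it) and 2440 for API5 minus API3 (1240 without it), pairs of dates outside the comparisons listed here. Array weights gave 3210 (F, 4 dates), 2 (API3 minus API2) and 1414 (API4 minus API3). With fewer arrays, the 6 compared gave 0 (API3 minus API2; 977 unadjusted), 0 (API4 minus API3; 2811 unadjusted), 3 (API5 minus API4) and 1080 (API5 minus API2), and the 12 of 1 session 3 (API4 minus API3) and 41 (API5 minus API4). Without both doubted arrays there were 150 (F, 4 dates), 467 (API5 minus API2) and 20 (API5 minus API4). Without the filter there were 765 (F, 4 dates), 53 (API4 minus API3) and 35 (API5 minus API4), and with probes bright on all 15 arrays 0 (API3 minus API2; 751 unadjusted) and 38 (API5 minus API4). The filter on all 15 arrays removed CUST_2091_PI427606222, the call of API3 minus API2, before testing, so that loss is by construction. API4 minus API3 gave 296 with normexp, 324 with the deposited table and 83 with GC correction. API3 minus API2 gave 2 with normexp and 3 with trend and robust moderation. The F test within slides gave 27.

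Leaving out each array gave 4901 to 7041 (F, 5 dates), 192 to 1782 (F, 4 dates; under 1298 by over 1.5 times without any API2 array, API3 replicates 1 or 16, API4 replicates 16 or 17, or API5 replicates 1 or 16), 2324 to 4503 (API2 minus API1, lowest without API2 replicate 16), 1 to 3 (API3 minus API2; 3 without API1 replicate 17, 2 without API3 replicate 1), 0 to 790 (API4 minus API3, each array but API3 replicate 17 moving it by over 1.5 times), 14 to 139 (API5 minus API4; 139 without API5 replicate 17, and 14 to 40 without API1 replicate 16, API2 replicates 16 or 17, API4 replicates 16 or 17, or API5 replicates 1 or 16), 4376 to 5941 (API5 minus API1) and 1274 to 3398 (API5 minus API2; under 2827 by over 1.5 times without any API2 array or API5 replicates 1 or 16). The 33 differences of named probes kept their direction in all 626 refits and their call in 561. These probes had been chosen for large differences of 1 sign in the same arrays. Single-probe differences outside these 33 were not followed through the settings. Some settings, such as the replicate block, leave a difference unchanged by construction. The kept directions are therefore no independent support. Dimness limits what remains: 2855 probes were not tested.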

Other observations

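The tests in this part were chosen after the data had been seen, apart from that of the spots around absent probes.

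Probes that differed among the 4 later dates followed the calendar more often than an arbitrary order would give. Of the 1298 probes, 304 (23.4%) had a higher mean at each of the 3 steps and 315 (24.3%) a lower one, where each of the 24 possible orders would hold 4.17% if all were alike. July 3 held the highest mean of 203 and the lowest of 254. A difference between the slide of April 30 and May 22 and that of July 3 and September 11 would favour such orders too. Among all pairs of these dates the number of probes called was 1 at 22 days apart, 125 at 42, 1380 at 64, 62 at 70, 1240 at 112 and 2827 at 134. With the replicate number as a block it was 1, 372, 2364, 126, 2440 and 4094. The pairs at 22 and 70 days apart each shared a slide, and all other pairs crossed slides. The counts therefore do not separate the days between dates from the slide.

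Tested probes that share a run of 25 bases without being identical moved together. Over 926 such pairs the differences correlated across pairs with r = 0.90 for API2 minus API1, 0.66 for API3 minus API2, 0.81 for API4 minus API3, 0.87 for API5 minus API4 and 0.94 for API5 minus API1. Pairs are not independent replicates.

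The replicate numbers differed from each other across the season. With dates in the model, 1711 probes differed among the 3 numbers, and 1 of 100 splits within dates, the real one, gave as many (highest other 330). An arbitrary assignment of numbers within dates thus did not give such a count in these splits. Each number lay in the same array column on every slide. A column effect would set the real split apart as well, and the splits cannot part number from column. In all, 66 probes were well above background on all 10 arrays of 2 numbers and on none of the 5 of the third (25 absent in number 1, 26 in number 16 and 15 in number 17), and 22 were well above background in 1 number alone (5, 11 and 6). A local defect at the same place on the arrays of a number could dim such probes. The 66 lay at a median deviation of -6.40 on the log2 scale from the other numbers, whereas the spots within 3 rows and columns of theirs lay at 0.0084 (SD 0.076 over the probes), which argues against that. A candidate explanation is a difference in expression or sequence between the trees sampled. It was not tested, and the labels do not say that a number marks a tree.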
